A study of Sus scrofa with 6 samples.

How the data were processed

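The data were RNA-seq libraries of porcine (Sus scrofa) oocytes at metaphase of the second meiotic division (MII), 3 from control oocytes and 3 from oocytes exposed to malathion during in vitro maturation. Per the labels' protocols, malathion was added to the maturation medium at 1 mM from a 0.75 M stock in DMSO, polyadenylated RNA was amplified with a slightly modified Smart-seq2 method, and libraries were finished with a TruSeq DNA kit. Smart-seq2 copies whole polyadenylated transcripts from very small inputs and amplifies them by PCR, without molecular identifiers and without marking the strand. The labels do not say how many oocytes went into a library, or whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

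The deposited files hold 1 column of read counts per library, and the authors did no normalization that the files show. Per the submitters' processing notes, the tools were STAR 2.5.3a, HTSeq 0.9.1 and DESeq2 1.20.0. The role of each, the genome build, the annotation and the strand setting were not given in the sources used here. Each file lists 25880 Ensembl genes and 5 rows in which HTSeq collects reads given to no gene. These 5 rows held 36.7% to 42.6% of the reads of a file and were kept out of library sizes and tests. Reads given to no annotated feature made up 16.9% to 25.9% and reads aligned to more than 1 place 2.45% to 8.37% of a file. Genes with near-identical copies, such as those of ribosomal proteins with their many processed pseudogenes, can lose reads to the latter row, so their levels are uncertain. Overlapping and antisense genes cannot be told apart in counts made without strand. A table of gene names gave a symbol to 14857 of the 25880 identifiers, and a second table added 0. No coordinates are printed, because no genome build is named.

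Total gene counts ranged from 25816040 to 42312341 per library. CPM are counts scaled to these totals. Normalised CPM were computed with TMM factors, which ranged from 0.138 to 3.59 and were lowest in both replicate 3 libraries. Shares of counts carried Wilson 95% confidence intervals of at most ± 0.0161 percentage points for gene counts and ± 0.0147 for all reads of a file. These intervals cover counting error only, since PCR copies are not independent molecules. To compare detection at equal depth, each library was thinned at random to 25816040 counts. The chi-square over genes divided by its degrees of freedom was at least 61.8 for each of the pairs of libraries, so no library was present in duplicate.

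Malathion and control were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using the quasi-likelihood F test on the deposited counts with TMM factors and filterByExpr (minimum count 10, minimum total count 15), two-sided, with Benjamini-Hochberg adjustment over the 10678 genes kept and a threshold of 0.05. Correlations and the log2 ratios of single pairs of libraries used log2 CPM with a prior count of 2. Log2 fold changes are malathion minus control, standard errors were derived from the F statistic, and confidence intervals are at 95%. Fixed gene lists (23) were written before the data were examined, and 22 had at least 5 tested members. The list of melatonin synthesis and receptor genes had 4 and was not tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 22 lists. The ribosomal protein list takes paralogs such as RPL10L and RPS27L by its naming rule, and the list of nuclear genes of oxidative phosphorylation takes assembly factors whose symbols begin with NDUFA. Library measures were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

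The genes named in the text were set by a rule fixed before the data were examined. Since fewer than 6 genes were called, the first part of the rule took the 6 genes with the smallest p in each direction that had a symbol and a mean of at least 10 CPM, read as TMM-normalised CPM. Read as CPM on library totals, the rule would keep 8 of these 12 genes and name 4 others. The second part was to take, for each described list, the 2 members with the smallest p. It was applied only to the lists whose members are named in the text. The other lists are given by their splits and medians. The third part named GDF9, BMP15, ZP3, SOD1, CAT, GPX4, BAX, BECN1, CCNB1 and MOS whatever their result, and 1 further gene that is not reported here. GPX4 (ENSSSCG00000024052) had 0 counts in each of the 6 libraries and was not tested, and BAX was matched to no identifier in the name table. Genes named as the most abundant of a library were chosen after their values were seen.

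Control and malathion libraries share replicate numbers, and no label says what a number marks. The deviations of same-numbered libraries from their group means correlated across genes, at r = 0.466 for replicates 1, 0.467 for replicates 2 and 0.573 for replicates 3. The numbers were taken as a possible pairing of the samples, and the main fit used the group only. In these deviations each library correlated best with its own number. The margin was small between replicates 1 and 2, where control replicate 1 and malathion replicate 2 gave r = 0.457, so the pairing mainly parts the replicate 3 libraries from the others. Deviations within a group cancel out, so the far-off replicate 3 libraries raise r among replicates 1 and 2 however these pair. In log2 normalised CPM itself, control replicate 1 lay closer to malathion replicate 2 (r = 0.974) than to malathion replicate 1 (r = 0.954). Malathion replicate 2 lay closer to control replicate 1 than to control replicate 2 (r = 0.851). A pairing of replicates 1 and 2 is therefore not shown. A fit with the replicate number as a block was run as an alternative.

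The edgeR script was tested on simulated counts drawn with the means, depths and spread of these libraries. With 50 genes changed at each size among 9879 tested, it recovered 0% of 4-fold, 6% of 16-fold, 26% of 64-fold and 52% of 256-fold changes, and it called 2 of 9633 unchanged genes. With a dispersion of 0.1 in place of the observed one, it recovered 96% of 4-fold changes. A simulated 2-fold change of the ribosomal protein list passed camera at the preset correlation (adjusted p = 8.39e-05) and did not pass at the estimated one (adjusted p = 0.863), so the latter missed a change of that size in this draw. Simulated genes were drawn independently, while the real list had an estimated correlation of 0.254. The simulation thus does not show how either setting performs on correlated genes. Alternatives covered other normalisation factors, other filters, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, leaving out mitochondrially encoded genes, the block, robust estimation and leaving out each library in turn. Of the alternatives, 3 were added after seeing the data: leaving out both replicate 3 libraries, leaving out these and control replicate 2, and a term for replicate 3. Figures were drawn with matplotlib 3.10.9.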

Results

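The stored mRNA of pig oocytes matured in vitro was measured by RNA-seq with and without malathion, an organophosphate insecticide that inhibits acetylcholinesterase. The 6 libraries came from MII oocytes, 3 control and 3 malathion-treated. Total gene counts were 27788154, 27105849 and 29471856 in control replicates 1, 2 and 3, and 25816040, 27770242 and 42312341 in malathion replicates 1, 2 and 3. A fully grown oocyte makes little new RNA, so these counts reflect mainly maternal transcripts stored during growth and their use and decay during maturation.

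Transcripts of a mature oocyte were among the most abundant in control replicate 1 and malathion replicates 1 and 2. DNMT1 (ENSSSCG00000013659), the maintenance DNA methyltransferase, stood at 37420 CPM in control replicate 1 and at 37340 and 29410 CPM in malathion replicates 1 and 2. BTG4 (ENSSSCG00000015020), an adaptor that brings maternal mRNA to the deadenylase, stood at 34830, 44540 and 24610 CPM in the same libraries. WEE2, an oocyte kinase that restrains CDK1, and KPNA7, an oocyte importin, lay between 9635 and 12860 CPM and between 8014 and 11380 CPM there. The linker histone H1-8 lay between 7585 and 9604 CPM. Markers of cumulus and granulosa cells summed to 689, 473 and 40.4 CPM in control replicates 1, 2 and 3, and to 724, 761 and 70.6 CPM in malathion replicates 1, 2 and 3, most of it VCAN and KITLG. The cumulus genes HAS2, PTX3 and FSHR stayed at or below 2.16 CPM in each library. Other markers of the list were present and uneven. CYP11A1 stood at 22.1 CPM in control replicate 1, 0.590 CPM in control replicate 2, and 18.2 and 81.6 CPM in malathion replicates 1 and 2. STAR reached 25.0 CPM in malathion replicate 2. Markers of theca, stroma, blood and endothelium summed to 28.1 CPM at most.

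**Figure D1:**
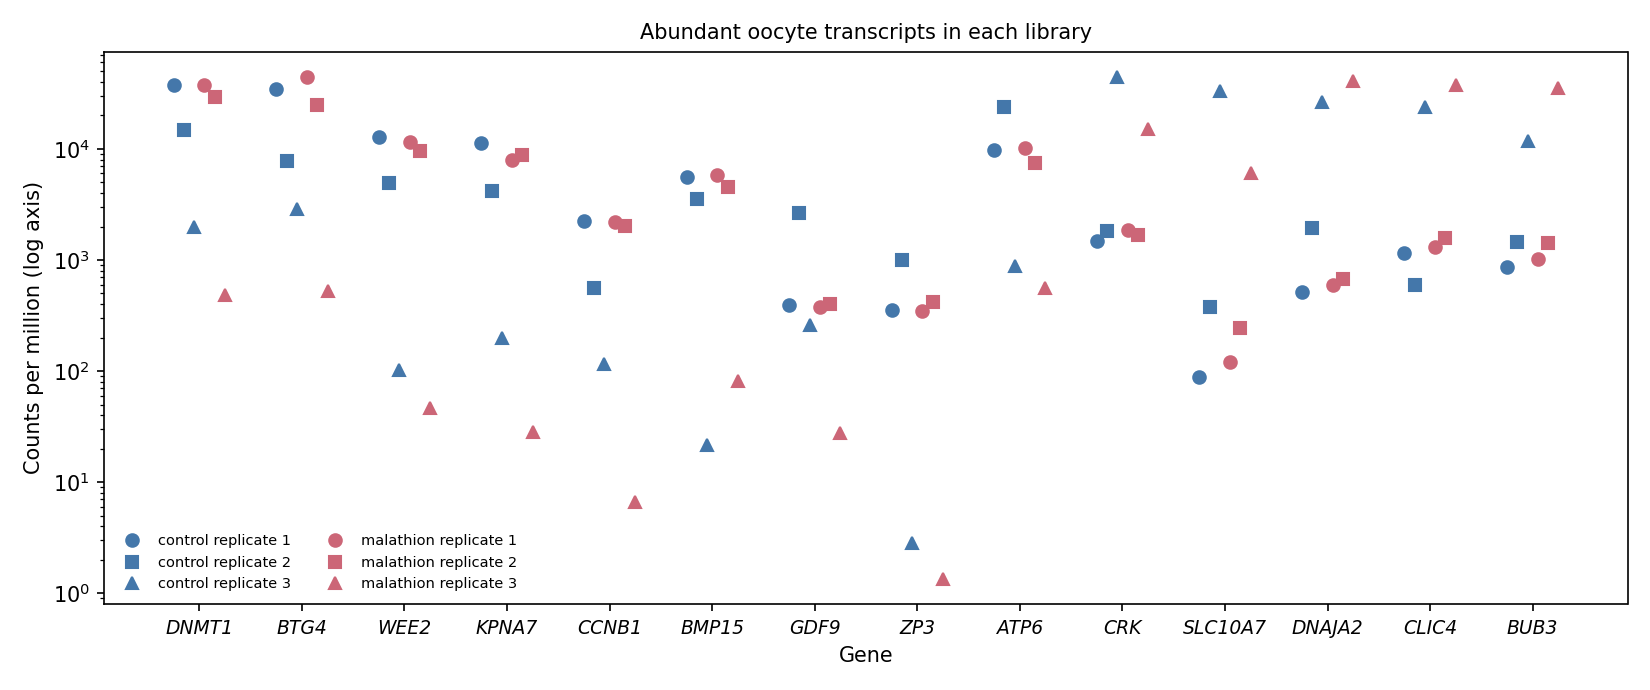
CPM (counts scaled to the library total) on a log axis for 14 abundant genes in each of the 6 libraries, with control in blue, malathion in red and the marker shape giving the replicate number. Control replicate 1 and malathion replicates 1 and 2 lie close together, while in both replicate 3 libraries WEE2 lies at or below 101.9 CPM and CRK, DNAJA2 and CLIC4 lie at or above 14980 CPM.

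Control replicate 2 and both replicate 3 libraries held other proportions of these transcripts. In control replicate 2, BTG4 stood at 7710 CPM, CCNB1, the cyclin of maturation-promoting factor, at 563 CPM against 2037 to 2248 CPM in control replicate 1 and malathion replicates 1 and 2, and the egg coat gene ZP2 at 145 CPM against 547 to 594 CPM. GDF9, the oocyte growth factor, stood there at 2650 CPM against 377 to 404 CPM, ZP3 at 998 CPM against 348 to 417 CPM, and the mitochondrial gene ATP6 at 24010 CPM against 7437 to 10150 CPM. In control replicate 3 and malathion replicate 3, BTG4 was down to 2880 and 521 CPM, WEE2 to 102 and 47.0 CPM, and ZP3 to 2.82 and 1.35 CPM. The same 2 libraries were led by genes of moderate level elsewhere. The adaptor gene CRK stood at 44660 and 14980 CPM there and at no more than 1871 CPM elsewhere, the chaperone gene DNAJA2 at 26250 and 40610 CPM against at most 1955 CPM, and the checkpoint gene BUB3 at 11700 and 35320 CPM against at most 1455 CPM.

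The replicate 3 libraries detected the fewest genes. At least 1 count was found for 14099, 14707 and 8344 genes in control replicates 1, 2 and 3, and for 12211, 13589 and 8492 genes in malathion replicates 1, 2 and 3. After thinning to equal depth, the numbers were 14041, 14685 and 8159 in the control and 12211, 13540 and 7982 in the malathion libraries. The 10 most abundant genes held 26.8% and 26.7% of the counts in the replicate 3 libraries and 10.3% to 22.3% in the others. Mitochondrially encoded genes held 2.81%, 5.89% and 0.560% of the counts in the control and 2.87%, 1.86% and 1.31% in the malathion libraries. Ribosomal protein genes held 0.158%, 0.702% and 0.221% in the control and 0.154%, 0.199% and 0.177% in the malathion libraries. None of 12 such library measures differed between the groups in an exact two-sided permutation test (p from 0.3 to 1, adjusted p from 0.96 to 1, smallest possible p 0.1). The number of genes detected was 12383 ± 3511 in control and 11431 ± 2637 in malathion libraries (SD, n = 3 each).

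**Figure D2:**
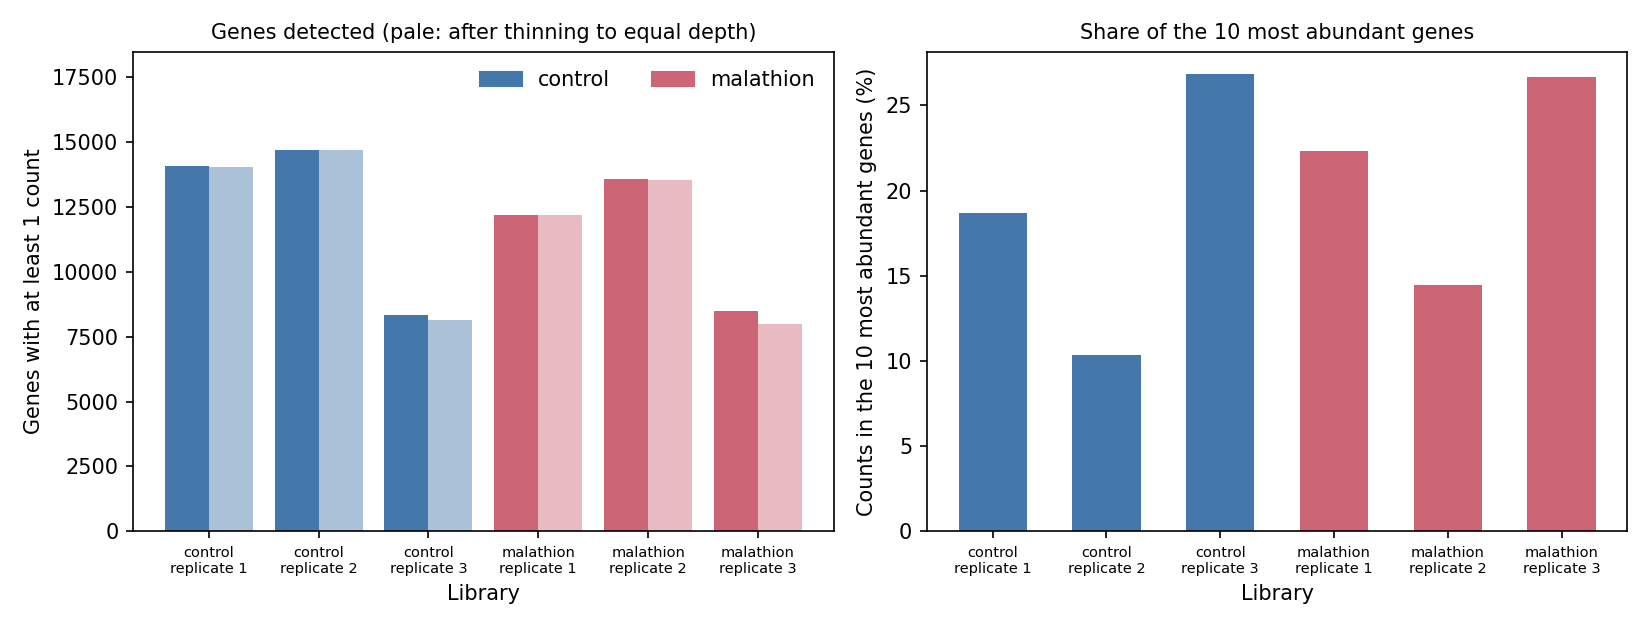
Left, the number of genes with at least 1 count in each library as deposited (full colour) and after thinning to 25816040 counts (pale); right, the percentage of counts in the 10 most abundant genes. Both replicate 3 libraries detect at most 8492 genes, against at least 12211 in each other library.

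Across genes, log2 normalised CPM of control replicate 1 correlated with malathion replicate 1 at r = 0.954 and with malathion replicate 2 at r = 0.974. These malathion libraries correlated with each other at r = 0.948. Control replicate 2 correlated with these 3 libraries at r = 0.818 to 0.851. The replicate 3 libraries correlated with each other at r = 0.802 and with the other 4 libraries at r = 0.635 to 0.724. The first principal component held 67.2% of the variance and parted the replicate 3 libraries from the rest, the second (21.3%) parted control replicate 3 from malathion replicate 3, and the third (8.22%) set control replicate 2 apart. Genes are not independent replicates, so these values describe the libraries.

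**Figure D3:**
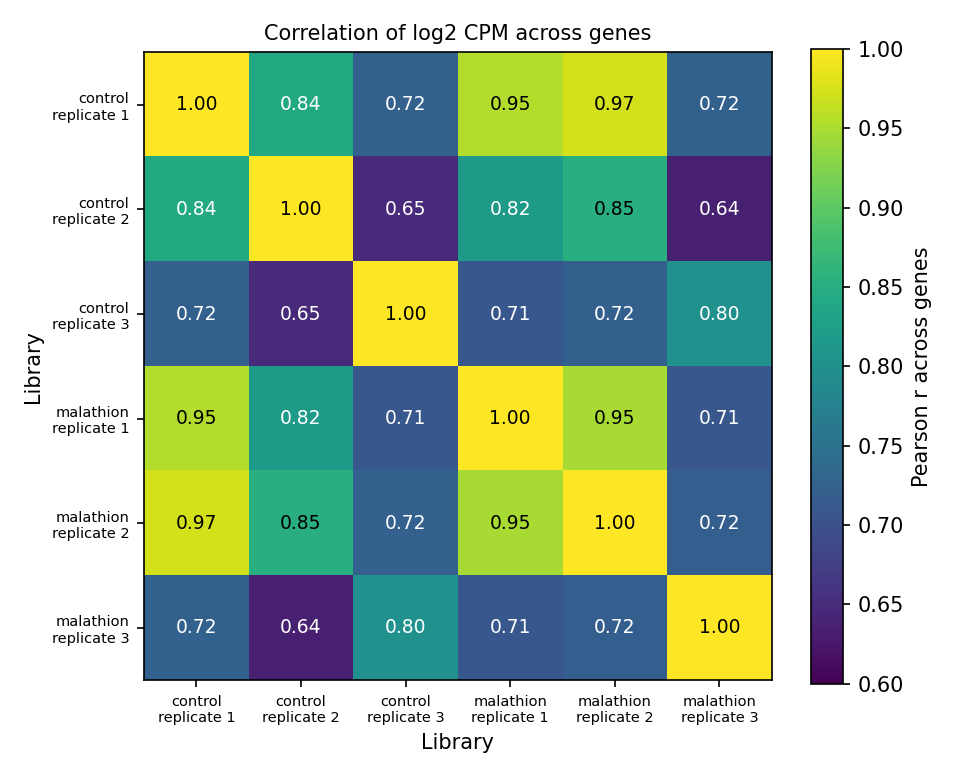
Pearson correlation across genes of log2 normalised CPM for each pair of the 6 libraries, from 0.6 (dark) to 1 (light). Control replicate 1 lies as close to malathion replicates 1 and 2 (0.95 and 0.97) as these lie to each other (0.95), and the replicate 3 libraries correlate with the other libraries at 0.72 or less.

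The comparison of malathion with control asked how the insecticide affected the mRNA stored in oocytes. Over the 1424 genes at a mean of at least 100 CPM, the log2 ratio of malathion to control (CPM plus 1) had an SD of 0.28 in replicates 1, 1.11 in replicates 2 and 3.43 in replicates 3. In replicates 1, GDF9 stood at 393 CPM in control and 377 CPM in malathion replicate 1, BMP15, another oocyte growth factor, at 5523 and 5810 CPM, the sperm-binding egg coat gene ZP3 at 352 and 348 CPM, and CCNB1 at 2248 and 2211 CPM. BTG4 stood at 34830 and 44540 CPM there, KPNA7 at 11380 and 8014 CPM and MOS at 339 and 282 CPM. Over the 3 against 3 libraries, the log2 fold change was −2.41 ± 1.61 (SE) for GDF9 (ENSSSCG00000014288), 0.49 ± 1.90 for BMP15 (ENSSSCG00000012310), −0.48 ± 1.28 for ZP3 (ENSSSCG00000007691) and −0.10 ± 1.65 for CCNB1 (ENSSSCG00000029326). MOS (ENSSSCG00000006248), the kinase that holds the MII arrest, stood at 282 to 388 CPM in 4 libraries, at 2.85 CPM in control replicate 3 and at 1458 CPM in malathion replicate 3 (log2 fold change 5.35 ± 2.68). None of these 5 genes passed the test. GDF9 stood at −1.38 without control replicate 3, and MOS at 0.62 without malathion replicate 3. The fold changes rest on TMM factors, so they do not follow from the CPM printed here. In normalised CPM, MOS stood at 10560 in malathion replicate 3, and GDF9 at 1846 in control replicate 3 against 259 CPM on the library total. With library totals alone the fold change was 1.58 for MOS and −2.04 for GDF9.

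No gene of the 10678 tested passed edgeR's quasi-likelihood test at an adjusted p of 0.05 (smallest adjusted p 0.9998). An unadjusted p under 0.05 was found for 383 genes (98 higher and 285 lower after malathion), against 534 expected by chance. DESeq2, limma-voom and edgeR's likelihood ratio test called 0 genes too, with 227, 110 and 685 genes at an unadjusted p under 0.05. DESeq2 gave no p for 1119 genes, so these were left untested there. The control and malathion values did not overlap for 302 genes, or 2.83%, against 10% given by chance if all 6 libraries could be exchanged. The other 3 splits that part each pair of same-numbered libraries gave 300 to 397 genes. Fold changes were loosely bounded, since the biological coefficient of variation was 1.10 and the 95% interval of a log2 fold change had a median half-width of 3.02. Without both replicate 3 libraries, an alternative added after seeing the data, 0 genes passed with 253 at an unadjusted p under 0.05. Without either malathion replicate 1 or malathion replicate 2, 3 genes passed, SMYD2, CTSF and ENSSSCG00000009366, each at its highest in malathion replicate 3. Without the filter on low counts 60 genes passed.

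None of the genes with the smallest p passed the test. Of the 383 genes at an unadjusted p under 0.05, 283 had over 90% of their normalised CPM in 1 library. By library, 240 had their highest normalised CPM in control replicate 3, 97 in malathion replicate 3, 45 in control replicate 2 and 1 in malathion replicate 1. TMM factors of 0.1405 and 0.1381, against at least 2.254 in the other libraries, raise normalised CPM in control replicate 3 and malathion replicate 3. No share over all tested genes is given here, so these counts are not shown to be particular to the genes with a small p. The 6 with the smallest p and a higher value after malathion were SMYD2 (ENSSSCG00000015583), a lysine methyltransferase (log2 fold change 8.40 ± 2.32, SE), CTSF (ENSSSCG00000038918), the lysosomal protease cathepsin F (7.51 ± 2.22), MMRN1 (ENSSSCG00000009202, 5.94 ± 1.80), NTPCR (ENSSSCG00000010166, 5.97 ± 1.83), PAPSS2 (ENSSSCG00000010437), an enzyme of sulfate activation (7.33 ± 2.32), and DIO1 (ENSSSCG00000028896), a deiodinase of thyroid hormone (9.10 ± 2.90). Each was highest in malathion replicate 3. SMYD2 had 2690 counts there and at most 53 in any other library, and DIO1 had 14034 against at most 122. Without malathion replicate 3, the log2 fold changes of the 6 genes lay between −0.23 for DIO1 and 0.68 for MMRN1. The 6 with a lower value were MRPS11 (ENSSSCG00000037343), a protein of the mitochondrial ribosome (−6.40 ± 1.72), SLC38A1 (ENSSSCG00000000807), an amino acid transporter (−7.70 ± 2.16), the kinase gene MAP3K12 (ENSSSCG00000000275, −7.46 ± 2.10), DEF8 (ENSSSCG00000002640, −9.11 ± 2.58), the ribosomal protein gene RPS7 (ENSSSCG00000031088, −7.32 ± 2.09) and TMEM161A (ENSSSCG00000033168, −9.88 ± 2.83). Each was highest in control replicate 3 by normalised CPM. TMEM161A had 4697 counts there and at most 78 elsewhere, and MRPS11 had 427 counts there and 4371 in control replicate 2 against at most 75 elsewhere. Without control replicate 3, MRPS11 stood at −5.24 and the other 5 genes between −1.90 for RPS7 and −0.30 for DEF8. These sizes also depended on the scaling and the design. With library totals alone the 6 genes with higher values ranged from 2.05 to 5.55 (SMYD2 4.39, CTSF 3.41) and the 6 with lower values from −6.12 to −4.02, and with the replicate number as a block from 1.64 to 2.39 and from −4.98 to −2.12. DESeq2 gave no p for 11 of the 12.

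**Figure D4:**
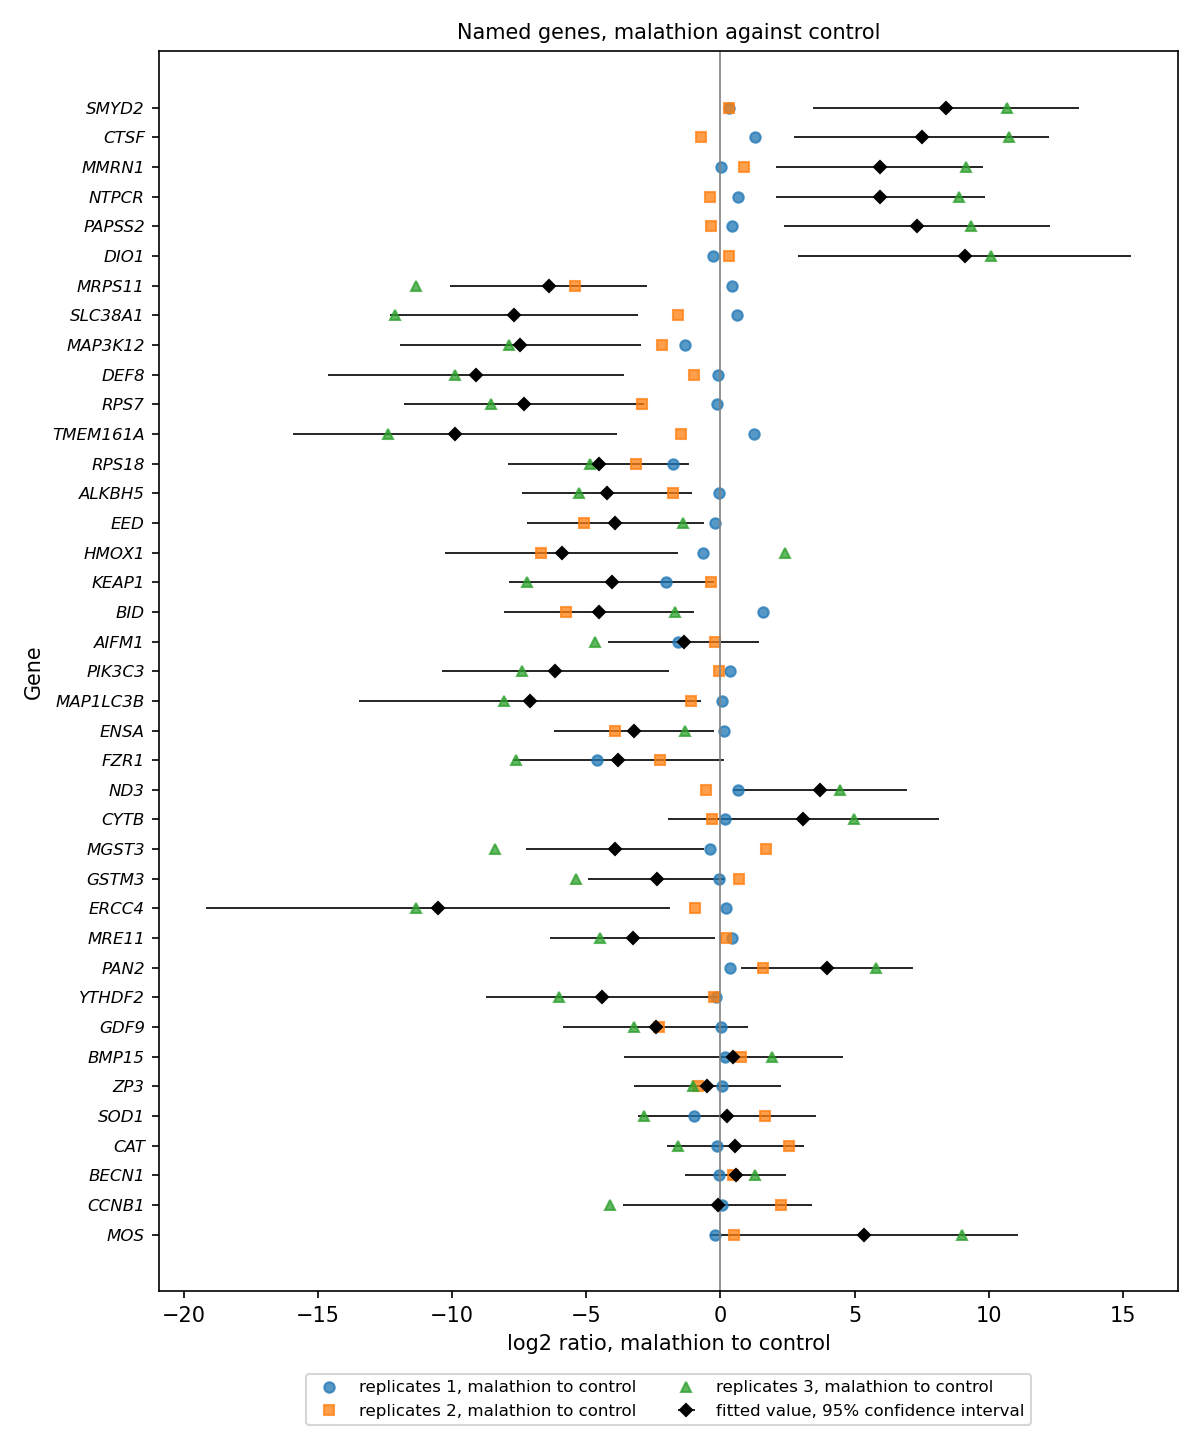
Log2 ratio of malathion to control for the 39 named genes that were tested. Black marks give the value fitted over 3 against 3 libraries with its 95% confidence interval. Other marks give the ratio in normalised CPM of the libraries with replicate number 1 (circles), 2 (squares) and 3 (triangles). The ratios of replicates 1 lie near 0 for most genes, and those of replicates 3 are mostly the farthest from 0; no gene passes the adjusted threshold.

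Genes of cytosolic ribosomal proteins, the structural proteins of the translation machinery, were the only list of 22 to pass camera. Of the 46 members tested, 38 were lower and 8 higher after malathion, with a median log2 fold change of −1.40 (adjusted p = 2.57e-08). The call was lost with an estimated correlation (adjusted p = 0.819), fry passed 0 lists, and 0 members were called over all genes or adjusted over the list alone. RPS7 had 3540 counts in control replicate 3, 1138 in control replicate 2 and at most 125 elsewhere, and RPS18 (ENSSSCG00000001502) had a log2 fold change of −4.54 ± 1.57 (−2.26 without control replicate 3). Control replicate 2 held the highest normalised CPM for 26 of the 46 genes and control replicate 3 for 10. The median log2 ratio of malathion to control in normalised CPM was −0.16 in replicates 1, −1.63 in replicates 2 and −0.77 in replicates 3. Without control replicate 2, 29 genes were lower and 17 higher (camera adjusted p = 0.0227, and 0.996 with an estimated correlation). The median without that library was −0.19, against 0.22 for all tested genes. Without this library and both replicate 3 libraries the median was −0.02 (adjusted p = 0.930).

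**Figure D5:**
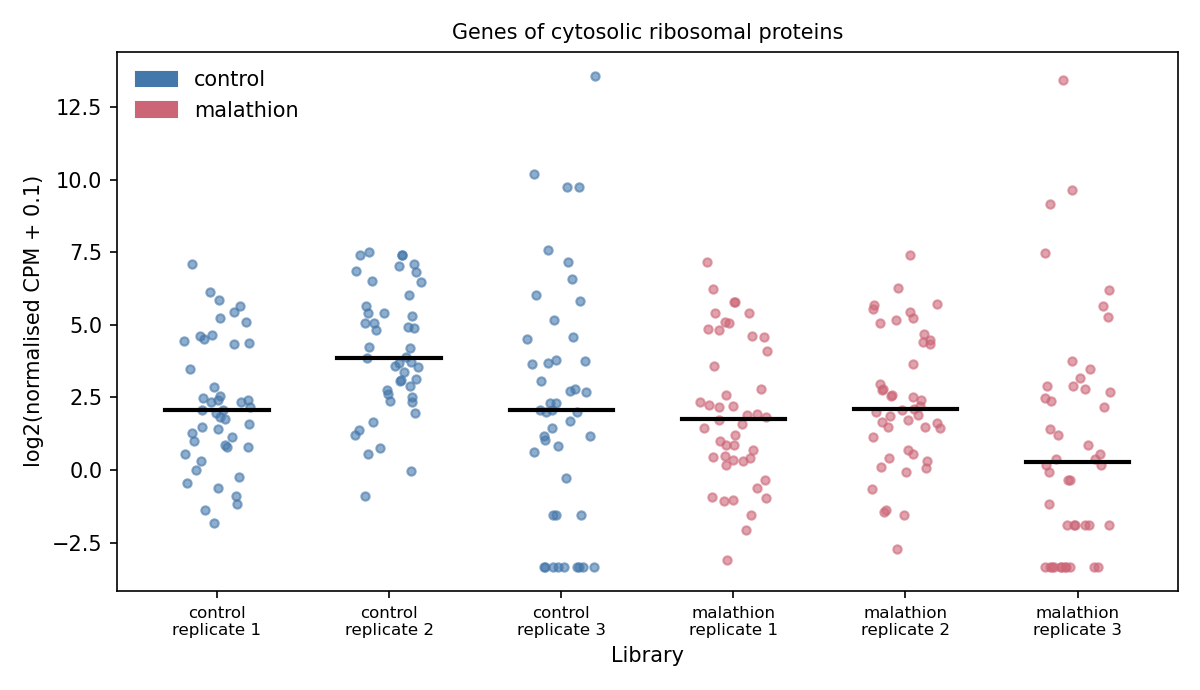
Normalised CPM of the 46 tested ribosomal protein genes in each library, as log2 of the value plus 0.1, with 1 point per gene and the median as a black bar; control is blue and malathion red. The bar of control replicate 2 is the highest of the 6 (median normalised CPM 14.5, against 1.11 to 4.15 in the other libraries).

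The lists for oocyte functions did not pass, and neither did any other (camera adjusted p from 0.172 to 0.601 over the other 21 lists, and 0.819 for each list with an estimated correlation). None of their members was called over all genes or adjusted over the list alone. The median of 15 of the 22 lists changed sign when 1 library was left out, of 8 lists without control replicate 2. Without that library the median log2 fold change of all tested genes moved from −0.08 to 0.22, so turns upward there partly follow a shift common to all genes. For maternal mRNA storage, polyadenylation and decay, 30 of 48 members were higher after malathion and 18 lower (median log2 fold change 0.12). The direction turned without malathion replicate 3 (19 higher and 31 lower, −0.36), without control replicate 3 (−0.04), without malathion replicate 2 (−0.08) and with library totals alone (16 and 32, −0.15). PAN2 (ENSSSCG00000000393), a deadenylase subunit, had a value of 3.99 ± 1.498, and YTHDF2 (ENSSSCG00000027686), a reader of methylated mRNA, of −4.43 ± 2.02. PAN2 stood at 0.90 without malathion replicate 3 and YTHDF2 at −0.21 without control replicate 3. Oocyte identity genes were split 11 to 9 (median 0.05, from −0.13 to 0.39 when leaving out 1 library), and genes of the egg coat, cortical granules and sperm binding 6 to 11 (−0.39, and 0.18 without control replicate 2). For the meiotic cell cycle and spindle checkpoint, 23 of 38 members were higher (median 0.20, mean −0.08), with a median of −0.17 without control replicate 3 and −0.08 without malathion replicate 1. ENSA (ENSSSCG00000006653), an inhibitor of the phosphatase that opposes CDK1, had −3.23 ± 1.40 and 8094 counts in control replicate 2 against at most 403 elsewhere, and its sign turned without that library (0.33). FZR1 (ENSSSCG00000013481), an activator of the anaphase-promoting complex, had −3.81 ± 1.84, and −10.58 without malathion replicate 2. Spindle and actin genes were split 18 to 26 (−0.20, from −0.53 to −0.14 when leaving out 1 library). Among epigenetic regulators, 28 of 44 were lower (median −0.32, from −0.67 to −0.17 when leaving out 1 library, adjusted p = 0.172 over all libraries), with −4.22 ± 1.48 for the RNA demethylase gene ALKBH5 (ENSSSCG00000035120) and −3.92 ± 1.54 for the Polycomb gene EED (ENSSSCG00000014915). ALKBH5 stood at −0.84 without control replicate 3, and EED at −0.58 without control replicate 2. The control libraries in these splits include control replicate 2, with its low BTG4 and CCNB1, and control replicate 3, with its 8344 genes.

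The lists of oxidative stress, cell death and autophagy genes did not pass either. Among antioxidant genes, 14 of 32 were higher and 18 lower (median −0.22, and 0.09 without control replicate 2). SOD1 (ENSSSCG00000021355), the cytosolic superoxide dismutase, had a log2 fold change of 0.25 ± 1.55 and catalase, CAT (ENSSSCG00000013302), of 0.56 ± 1.19, with ranges of −0.88 to 1.39 and 0.10 to 1.80 when leaving out 1 library. HMOX1 (ENSSSCG00000039745), the stress-induced heme oxygenase, had −5.92 ± 2.03, with 3785 counts in control replicate 2 and at most 25 in any other library, and without that library its sign turned (0.59). KEAP1 (ENSSSCG00000023667), which holds the antioxidant regulator NFE2L2 in check, had −4.05 ± 1.78, and −1.78 without control replicate 3. Apoptosis genes were split 7 higher to 13 lower (−0.21), and 13 to 8 without control replicate 2 (0.23). AIFM1 (ENSSSCG00000012657) had −1.37 ± 1.31, and BID (ENSSSCG00000000769), a death-promoting BCL2 relative, had −4.53 ± 1.66 with 4089 counts in control replicate 2 and at most 55 elsewhere. AIFM1 stood at −0.84 without malathion replicate 3 and −2.48 without malathion replicate 2, and BID at −0.0825 without control replicate 2. Autophagy and lysosome genes were split 13 to 22 (−0.23, and 0.07 without control replicate 2). BECN1 (ENSSSCG00000017386) had 0.57 ± 0.88, with 0.369 without malathion replicate 3 and 0.013 with library totals alone. PIK3C3 (ENSSSCG00000003749) with −6.15 ± 1.98 and MAP1LC3B (ENSSSCG00000002655) with −7.11 ± 2.98 were carried by control replicate 3, without which they stood at 0.37 and −0.13.

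Among genes of mitochondria, detoxification and DNA repair, no list passed in the 3 against 3 libraries. The 13 mitochondrially encoded genes of oxidative phosphorylation were split 7 higher to 6 lower (median 0.33, −0.45 without malathion replicate 3 and −0.52 with library totals alone), with 3.70 ± 1.51 for ND3 (ENSSSCG00000018084) and 3.09 ± 2.36 for CYTB (ENSSSCG00000018094). Both were highest in malathion replicate 3 by normalised CPM, and without it they stood at −0.49 and 0.15. By CPM, CYTB was higher in control replicate 2 (1920) than in malathion replicate 3 (1565). With library totals alone ND3 stood at 1.01 and CYTB at 0.32. Nuclear genes of oxidative phosphorylation were split 23 to 36 (−0.39) and genes of mitochondrial dynamics 8 to 12 (−0.18). Without control replicate 2 both turned, to 45 higher and 14 lower (0.36) and to 14 and 6 (0.24). The median of all tested genes was 0.22 in that fit, so the turn of the mitochondrial dynamics genes is not particular to them. Xenobiotic and organophosphate metabolism genes were split 14 to 9 (median 0.12, mean −0.09, the median from −0.28 to 0.99 when leaving out 1 library), with −3.93 ± 1.55 for MGST3 (ENSSSCG00000006325) and −2.38 ± 1.199 for GSTM3 (ENSSSCG00000006821), both glutathione transferases, the latter from a family of similar copies. DNA damage genes were split 26 to 21 (median 0.18, mean −0.19), with a median of −0.13 without malathion replicate 1, −0.02 without malathion replicate 2 and −0.05 with library totals alone. ERCC4 (ENSSSCG00000007881), a nuclease of excision repair, had −10.54 ± 4.04, with 67551 counts in control replicate 3 and at most 359 elsewhere, and MRE11 (ENSSSCG00000014955), of double-strand break repair, had −3.27 ± 1.44. Without control replicate 3 these values were 0.21 and 0.53, and those of MGST3 and GSTM3 −0.0146 and −0.0712. Genes of endoplasmic reticulum stress were split 14 to 15 (median −0.07, with the test pointing upward), heat shock and immediate early genes 12 to 7 (0.43), proteasome genes 20 to 14 (0.25), lipid genes 12 to 14 (−0.45) and glycolysis genes 11 to 12 (−0.19). Leaving out 1 library gave medians of −0.32 to 0.40 for endoplasmic reticulum stress, 0.11 to 0.87 for heat shock, 0.09 to 0.51 for proteasome, −0.54 to −0.03 for lipid and −0.48 to 0.35 for glycolysis genes, and library totals alone gave −0.21 for heat shock genes. Cumulus and granulosa markers were split 10 to 3 (0.66), with 8 to 7 (0.10) without malathion replicate 3 and 10 to 6 (0.31) without control replicate 2. Without control replicate 1 their median rose to 1.525. Markers of theca, stroma, blood and endothelium were split 3 to 2 (0.16, from −0.26 to 0.21 when leaving out 1 library). Without control replicate 3, camera at the preset correlation passed the cumulus markers as higher (14 of 16) and the nuclear genes of oxidative phosphorylation as lower (45 of 61), with an adjusted p of 0.0425 for both. Neither call held with an estimated correlation (adjusted p = 0.789 for both).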

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

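The alternatives that leave out both replicate 3 libraries, these and control replicate 2, or add a term for replicate 3 were chosen after the result was seen; the others were planned. Each library held at least 25816040 counts, and the tests were not repeated at lower depth. The count of 0 genes changed, or changed at least 2-fold, held under each alternative except 3. Without a filter on low counts 60 genes were called, each at least 2-fold (15 higher, 45 lower); 44 of them were among the genes tested with the filter, and they were highest in control replicate 3 (27), control replicate 2 (18) or malathion replicate 3 (15). Leaving out 1 library gave 0 to 3 genes, with 3 without malathion replicate 1 or malathion replicate 2 (SMYD2, CTSF and ENSSSCG00000009366). In each of these settings edgeR pooled the spread of all genes nearly fully (median degrees of freedom 67410, 34140 and 33500, against 14.4). Library totals alone did so too (42710), with 0 calls at a higher common dispersion (2.44 against 1.22), and the cause was not tested further. Library totals alone moved the median log2 fold change of all genes by −0.26 and no filter by −0.20 from its −0.08. Leaving out control replicate 2 moved it most, by 0.297 to 0.22. The shift was −0.117 without control replicate 3, −0.158 without malathion replicate 1 and −0.174 without malathion replicate 2.

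The 1 gene list past camera became 0 with an estimated correlation, and 1 to 3 when leaving out 1 library, with 3 without control replicate 3, of which 0 held with an estimated correlation. For the ribosomal protein genes, the adjusted p was 0.819 with an estimated correlation. At the preset correlation it ran from 4.03e-09 to 0.0227 when leaving out 1 library, the highest without control replicate 2, and the other fits lay within that range, except 1. In that fit, without both replicate 3 libraries and control replicate 2, it was 0.930 and the test pointed upward. This fit of 1 control against 2 malathion libraries, in which the lone control is assumed to vary like the others, passed the mitochondrially encoded genes as lower (adjusted p = 7.65e-06), where the fit on all libraries pointed higher. That call was lost with an estimated correlation (adjusted p = 0.931). The median of 7 of the 22 lists kept its sign when each library was left out in turn. It changed sign for 5 lists with library totals alone, for 1 with DESeq2 size factors and for 0 with upper quartile factors. Library totals alone also moved the median of all genes by −0.26, so these sign changes partly follow a shift common to all genes. The fit with the replicate block called 0 genes with 120 at an unadjusted p under 0.05, left the ribosomal protein genes lower (median −1.10, adjusted p = 5.45e-09, and 0.771 with an estimated correlation) and changed no call. It turned the medians of oocyte identity (−0.29), mitochondrially encoded (−0.11), xenobiotic (−0.04), endoplasmic reticulum stress (0.06) and lipid genes (0.06).

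Of 736 log2 fold changes of named genes with an adjusted p under alternatives, 674 kept direction and side of the threshold, 17 gained a call and 45 changed sign. DESeq2 gave no p for 26 of the 39 named genes, whose direction stayed. Of the 39 genes, 37 came nearer 0 by over 1.5 times or changed sign without 1 library, 26 did with library totals alone, 26 with limma-voom and 30 with the replicate block. Farther from 0 by over 1.5 times without 1 library were 7. The cause of these sign changes was not tested, beyond what leaving out a library shows. Without both replicate 3 libraries, values were 0.19 for PIK3C3, −0.044 for CYTB, 0.49 for MGST3, 0.34 for GSTM3, 0.34 for MRE11 and 0.66 for CCNB1. Without these and control replicate 2, they were −0.27 for MMRN1, 0.88 for MRPS11, 0.81 for SLC38A1, 0.23 for DEF8, 0.83 for TMEM161A, 0.11 for HMOX1, 1.71 for BID, 0.15 for PIK3C3, 0.59 for ENSA, −0.0799 for CYTB, 0.22 for GSTM3, 0.20 for MRE11, −0.13 for BMP15, 0.0704 for ZP3, −0.23 for SOD1, −0.0193 for CAT, −0.0150 for BECN1 and −0.0785 for MOS. SOD1 stood at −0.70 with limma-voom, −0.0765 with the replicate block and −0.0282 with the term for replicate 3. CAT stood at −0.0249 with limma-voom, and CCNB1 at 0.54 with library totals alone. Leaving out 1 library gave ranges of −0.23 to 9.70 for DIO1, −6.54 to 0.59 for HMOX1, −6.72 to 0.37 for PIK3C3, −3.86 to 0.33 for ENSA, −0.49 to 4.32 for ND3, −11.12 to 0.21 for ERCC4, −3.82 to 0.53 for MRE11, −0.0282 to 1.52 for BMP15, −0.98 to 0.35 for ZP3, −0.88 to 1.39 for SOD1 and −0.66 to 0.46 for CCNB1. DESeq2 was not run on the gene lists. The number of genes detected stayed lower in malathion than in control at a minimum of 10 counts (−535, against −953 at 1 count) and after thinning (−1051), within the spread of the libraries. After thinning it was lower for each replicate number (14041 to 12211, 14685 to 13540 and 8159 to 7982). As deposited, replicates 3 went the other way (8344 to 8492). Library measures were not tested by pairs.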

Other observations

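The tests of depth and of other cell types in replicate 3, of cumulus cells and maturation in control replicate 2, and both tests of the ribosomal protein genes were chosen after the result was seen, and the criteria of the last pair were reset after their values were known. The others were set before.

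Control replicate 2 differed from control replicate 1 and malathion replicates 1 and 2 in several gene groups at once. In CPM on library totals, BTG4, WEE2, KPNA7, DNAJA1, CCNB1 and ZP2 were lower there, by 1.94 to 3.77 times against the lowest of the 3 libraries. On the same scale GDF9 was 6.57 times the highest of the 3, ZP3 2.39 times and ATP6 2.37 times. In median log2 normalised CPM, ribosomal protein genes were 1.63 to 2.24 higher there, and nuclear genes of oxidative phosphorylation 0.37 to 0.67 higher. These scales differ, since the TMM factor was 3.588 in control replicate 2 and 2.254 to 2.673 in the 3 libraries. A few genes nearly absent elsewhere were abundant in it, among them BID with 4089 counts against at most 55 and HMOX1 with 3785 against at most 25.

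The summed cumulus and granulosa markers there were 0.686 times the lowest of the 3 libraries, with VCAN at 286 CPM and KITLG at 133 CPM. Oocyte identity genes were lower as well, at 22913 CPM against at least 33978 CPM in the 3 libraries. With both lists down, the markers cannot exclude cumulus or granulosa RNA as the source of the difference. Depth is argued against: after thinning to equal totals, the highest correlation of control replicate 2 with the 3 libraries stayed 0.0968 below the lowest among them. A less advanced maturation may fit the higher GDF9 and ribosomal protein genes and the lower BTG4 and CCNB1. Nuclear genes of oxidative phosphorylation were higher by at least 0.365 in median log2 normalised CPM. Other oocyte genes did not go 1 way there. BMP15 stood at 3524 CPM against 4492 to 5810 CPM in the 3 libraries, and ZP2 was lower while ZP3 was higher. MOS, at 366 CPM, lay within the 282 to 388 CPM of the 3 libraries. The difference concerns 1 library, and the direction was known when the test was set. A less advanced maturation therefore cannot be told apart from another oocyte pool or library preparation.

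Both replicate 3 libraries detected few genes. Depth does not account for this, since at equal depth the higher of them detected 66.82% as many genes as the lowest of the other libraries. The higher of their summed cumulus markers was 0.149 times the lowest other library. Oocyte identity genes were lower as well, at 4711 CPM in control replicate 3 and 2631 CPM in malathion replicate 3 against at least 22913 CPM elsewhere. With both lists down, the markers cannot exclude RNA of other ovarian cells. An equal chance of loss for genes of like CPM is argued against by the genes lost. Of 1369 genes at 20 to 100 CPM in each other library, 94 and 116 had under 3 counts in control replicate 3 and malathion replicate 3. Missing from both were 35, 4.394 times the 7.97 expected (odds ratio 8.72, Fisher's exact p = 2.97e-16 across genes, and 3.41 times within 10 strata of abundance). Genes of like CPM can differ in their number of starting molecules, so a loss of molecules at random is not excluded by this. A loss that favours certain transcripts, or a state of the oocytes shared by the control and malathion libraries of this number, stays open too and was not tested. The levels of abundant genes still differed widely between these libraries (SD of the log2 ratio 3.43 over 1424 genes).

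For the ribosomal protein genes, control replicate 2 alone stays open as the cause. Without it the median went from −1.40 to −0.19. The median of all tested genes went from −0.08 to 0.22 there, so the move of the list partly follows a shift common to all genes. Without control replicate 2 the list passed camera at the preset correlation (adjusted p = 0.02272) but not at an estimated one (adjusted p = 0.996). The list did not pass at an estimated correlation on all libraries either (adjusted p = 0.819), so that result cannot speak for or against control replicate 2 alone. An effect of malathion in each pair stays open too, since the highest of the pair medians was −0.164, although control replicate 1 against malathion replicates 1 and 2 gave a median of −0.02 (22 genes higher and 25 lower, adjusted p = 0.930, pointing upward). These cannot be told apart with 3 libraries in a group: 2 of the 10 splits of the 6 libraries gave a set test p as small (1.17e-09 for the real split and 8.44e-10 as the smallest of the others, which parts 1 of the 3 pairs). Among the 4 splits that part all 3 pairs the real one had the smallest p, with 2.33e-08 to 0.364 in the others. The set test p followed control replicates 2 and 3. Each split that kept these on 1 side gave 0.00349 or less, also with a malathion library beside them (8.44e-10 and 2.33e-08). Each split that parted them gave 0.0856 or more. The small p of the real split therefore does not set malathion apart from these control libraries.

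The 6 libraries can be parted in 10 ways into 3 against 3, so the share of splits with a result as large cannot fall under 0.1, and these splits are too few for a share under 0.05. Each of the 10 splits gave 0 genes at an adjusted p under 0.05, and 0 changed at least 2-fold, as the real one did. All 10 gave at least the 383 genes of the real split at an unadjusted p under 0.05, up to 1955. The 4 splits that keep both replicate 3 libraries on 1 side gave 1379 to 1955, which points to a structure of the samples other than treatment. Among the 4 splits that part the 3 pairs, the others gave 385 to 406. The real split passed 1 gene list and the highest other split 2, and 4 of the 10 passed at least 1.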
